A study of Homo sapiens with 4 samples.

How the data were processed

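The series holds 4 ribosome profiling libraries from HEK293T cells, 2 of cells treated with DFMO alone (DFMO) and 2 of cells treated with DFMO and then given spermidine (Spermidine). All 4 were used. Per the labels, lysates were digested with RNase I, monosomes were collected on spin columns, and footprint libraries were made by a published protocol. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries. The same replicate number in both groups is not stated to mean a shared day, and it was used as a block only as an alternative.

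The deposited files hold expected counts of footprints per gene, which the authors did not normalize. Per the submitters' processing notes cutadapt and Bowtie were used. Their versions, the genome build, the annotation and the counting tool are not given in the sources used here, and no coordinates are therefore printed. Each file lists 39771 genes in 5 classes, of which 20424 are coding genes and 17019 are noncoding RNA genes, with 1081 pseudogenes, 892 long intergenic and 355 other transcripts. Reads that map to several places were shared between them, so all values are multiples of a sixth of a read. For coding genes the deposited counts, in another form of the same unit, are split into 3 columns without names. These were read as leader, coding region and trailer from the values, since the middle column holds nearly all reads of translated genes and the first is high for ATF4. It was checked that all values are 0 or above and that the regions of a gene do not sum to more than its whole count. Of the coding names, 18122 are symbols of the current gene table, and names are printed as the files give them.

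Coding counts were rounded to whole numbers. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, Spermidine against DFMO without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. TMM factors ran from 0.9906 to 1.01, and the biological coefficient of variation was 0.088. CPM are counts per 1000000 coding counts after TMM scaling. The standard error of a log2 change was taken as its size divided by the square root of F. A gene was taken to hold reads shared with other places if its coding count was not whole in any library. This was so for 4278 of the tested genes, and shared reads that add up to a whole count go unseen.

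The named genes follow a fixed rule. It takes the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean count of at least 50 and no overlap between groups. It adds all members of the lists of polyamine synthesis and breakdown, polyamine feedback and transport, and hypusine formation with a mean count of at least 10, and the 4 members with the smallest p of every other list. A gene that this rule takes is not reported here. The other lists cover cytosolic and mitochondrial ribosomal proteins, translation factors, tRNA synthetases, ribosome assembly, ATF4 targets, the unfolded protein response, heat shock, oxidative stress, metallothioneins, p53 targets, DNA replication, mitosis, histones, cholesterol synthesis, the respiratory chain, proteins of the mitochondrial genome, glycolysis and hypoxia, autophagy and lysosome, selenoproteins, the proteasome, immediate early genes, interferon response, and the folate cycle with nucleotide synthesis. Markers of blood, epithelial and mesenchymal cells stand for other cell types. Lists with at least 4 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, Benjamini-Hochberg over 25 lists), with an estimated correlation, and with fry.

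The leader and trailer ratios were tested as the interaction of region and treatment in edgeR with the library as a block. This covered genes that pass the coding filter and have at least 32 reads of the region over the 4 libraries, with 1 library size for both regions. Named are the 3 genes per direction with the smallest p, as 0 passed, and the tested genes among AZIN1, AMD1, ODC1, OAZ1, OAZ2, SAT1, PAOX, SMOX and ATF4. Ratios of single libraries carry a pseudocount of 0.5. Shares of regions were compared by an exact permutation test with both sides. Shares of single libraries have Wilson intervals at 95%, and the floor is 3 counts in a library, or over a group where a group is at 0. Intervals of ratios of low counts are exact binomial ones.

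The tests were run on simulated data of the same depth and spread, with genes drawn independently of each other. With 200 genes changed, the gene test called 32.3% of genes changed 1.5-fold, 78.6% of genes changed 2-fold and 0.01% of 11469 unchanged genes. In the real data 40.7% of tested genes were called, so these shares may not hold there. camera called a list of 30 genes raised 1.5-fold and 0 of 20 unchanged lists, and with an estimated correlation it did not call the raised list. As the simulated genes were independent, this does not test the preset correlation of 0.01. A 4-fold change of the leader ratio was called for 56.0% of genes and one of the trailer ratio for 3%.

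The alternatives tried were other scalings (median of ratios, library totals), no filter, a minimum mean of 50 counts, the replicate number as a block, leaving out each library, DESeq2 1.42.0, all regions summed, other read minimums and limma fits for the ratios, and shares without the 100 most abundant genes or only over genes that pass the filter. Thinning to the smallest coding total, leaving out genes with shared reads, scaling within regions and a term for region by replicate number were added after the data had been seen. Left out were rescaled values of other units, as the values are counts. Genes of noncoding classes were tested apart from coding genes.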

Results

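Ribosome footprints were counted in HEK293T cells, a human embryonic kidney line, after their polyamines had been lowered with difluoromethylornithine (DFMO). DFMO inhibits ornithine decarboxylase, the enzyme that makes putrescine, from which spermidine and spermine are built. All cells received 2.5 mM DFMO for 5 days. The 2 DFMO libraries came from cells given nothing further, and the 2 Spermidine libraries from cells that also received 2 mM spermidine during the last 24 hr. The comparison therefore asks which footprints differed once a polyamine had been given back. Untreated cells were not among the samples, so whether footprints returned to untreated levels was not tested. Ribosome profiling sequences the stretches of RNA that ribosomes protect from a nuclease, so a gene's count reflects how much of its mRNA was present and how many ribosomes each copy carried. Libraries of total mRNA were not analysed here, and these parts were not separated.

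The deposited counts summed to 6834608 for DFMO replicate 1, 8512909 for DFMO replicate 2, 13142164 for Spermidine replicate 1 and 11699280 for Spermidine replicate 2. Coding regions held 4873594, 3754578, 10262187 and 6611852 of them in the same order. Genes of noncoding classes took 25.8% of the counts in DFMO replicate 1 (95% Wilson interval 25.7 to 25.8) and 47.3% in DFMO replicate 2 (47.3 to 47.4). They took 19.2% in Spermidine replicate 1 (19.1 to 19.2) and 36.3% in Spermidine replicate 2 (36.2 to 36.3). These intervals, and all floors given here, cover counting error only. The replicate 2 library of each group thus stood apart from its replicate 1 library in noncoding share, and values within each replicate number are given beside the pooled ones where this bears on a measure. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.35 between the DFMO libraries and 4.84 between the Spermidine libraries.

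Genes of polyamine metabolism changed in both directions, and the list as a whole was not called (camera adjusted p = 0.928). AMD1, which makes the aminopropyl donor for spermidine and spermine synthesis, fell from 1631 ± 19.0 to 37.1 ± 0.610 footprints per 1000000 coding footprints (CPM; mean ± SD, n = 2 in each group here and below). This was a 44-fold decrease, the largest fall among the genes named by rule, with a log2 change of -5.46 (SE 0.10, edgeR adjusted p = 2.51e-12). ODC1, the target of DFMO, fell from 320.3 ± 22 to 181.9 ± 6.35 CPM (log2 change -0.82, edgeR adjusted p = 2.9e-05), and spermidine synthase SRM fell from 271.9 ± 24.5 to 162.9 ± 3.72 CPM (-0.74, 7.11e-05). Spermine synthase SMS did not pass (-0.02, 0.881), and ARG2, an arginase that supplies ornithine, rose (0.47, 0.0156). SAT1, the acetyltransferase that begins polyamine breakdown, rose from 8.86 ± 1.68 to 40.9 ± 2.54 CPM (4.68-fold, edgeR adjusted p = 8.07e-06), and its relative SAT2 rose 2.18-fold (0.00348). The polyamine oxidases SMOX and PAOX rose too, by a fitted log2 change of 3.18 (edgeR adjusted p = 0.00158) and 2.01 (0.0083), from counts near the floor. SMOX had 4 footprints in the DFMO libraries together and 72 in the Spermidine libraries, a ratio of 9.21 after scaling (95% counting interval 3.44 to 34.7), and its fitted log2 change was 3.98 without DFMO replicate 1. For PAOX the counts were 8 and 64 (ratio 4.09, 1.96 to 9.88).

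Antizymes and their inhibitor, which set the stability of ornithine decarboxylase, changed in both directions. Antizyme genes OAZ1 and OAZ2, whose full-length product needs a ribosomal frameshift, rose from 47.3 ± 5.96 to 212.7 ± 16.4 CPM and from 3.22 ± 0.436 to 37.1 ± 8.19 CPM. These were 4.51-fold and 11.3-fold increases (edgeR adjusted p = 2.69e-07 and 3.72e-06). Antizyme inhibitor AZIN1 fell from 341.0 ± 7.88 to 46 ± 9.79 CPM, a 7.49-fold decrease (3.53e-08), while AZIN2 had a log2 change of -0.20 and did not pass (0.653). Carriers linked to polyamine transport or its precursors fell. ATP13A2 and ATP13A3, ATPases of the polyamine-transporting P5B kind, changed by -0.87 and -0.75 on the log2 scale (edgeR adjusted p = 0.000137 and 8.59e-05). The heavy chain SLC3A2 changed by -0.94 (8.07e-06), the arginine carrier SLC7A1 by -1.19 (6.52e-06) and SLC12A8 by -1.62 (0.000723). SLC18B1 at -0.25 and GPC1 at 0.25 did not pass (0.123 and 0.332).

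**Figure D1:**
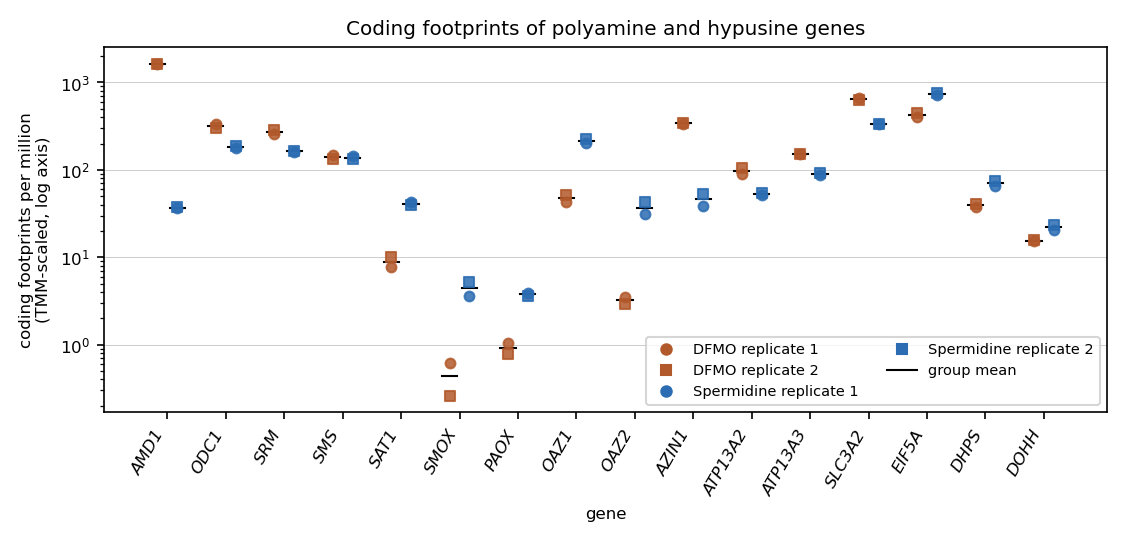
Coding footprint CPM (vertical log axis, TMM-scaled) of 16 genes of polyamine metabolism, its feedback and hypusine formation. Circles are replicate 1 and squares replicate 2, brown for DFMO and blue for Spermidine, and black bars are group means. AMD1 dropped from 1631 to 37.1, AZIN1 from 341.0 to 46, and OAZ2 rose from 3.22 to 37.1.

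Spermidine is the substrate for hypusine, a modified lysine found in the translation factor eIF5A. The genes for this factor and for both modifying enzymes rose. EIF5A went from 425.3 ± 25.1 to 742.6 ± 22.8 CPM (1.75-fold, edgeR adjusted p = 2.56e-05), deoxyhypusine synthase DHPS rose 1.78-fold (0.000373) and deoxyhypusine hydroxylase DOHH rose 1.42-fold (0.0447). EIF5AL1 also rose 1.75-fold, but it shares reads with EIF5A and was not measured apart from it. EIF5A2 had a log2 change of 0.87 and did not pass (0.0573). It passed without DFMO replicate 2 (edgeR adjusted p = 0.00992) and without Spermidine replicate 1 (0.0401). The DOHH call ended when any library was left out (edgeR adjusted p from 0.0917 to 0.241), with all regions summed (0.0987) and with all libraries thinned to the smallest coding total (0.253).

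Of the 13 tested members of the list of polyamine synthesis and breakdown, 5 rose, 5 fell and 3 did not pass. Adjusted over the list alone, 5 rose and 6 fell. Besides the genes above, the methionine salvage and supply genes MTAP and MAT2A fell (log2 change -0.34 and -0.35, edgeR adjusted p = 0.018 and 0.0235). MAT2B and AGMAT did not pass, with log2 changes of 0.08 and -0.89. Some of these calls ended when a library was left out. Without DFMO replicate 2 the edgeR adjusted p was 0.0527 for PAOX and 0.171 for MAT2A, without DFMO replicate 1 it was 0.0576 for ARG2 and 0.0776 for MTAP, and without Spermidine replicate 1 it ranged from 0.0562 for ARG2 to 0.197 for MAT2A over these 4 genes. For ARG2 it was also 0.107 without Spermidine replicate 2. The median of -0.02 and mean of 0.04 of this list differed in sign, and fry, unlike camera, called it as lower (adjusted p = 0.0301). In the list of feedback and transport genes 2 of 11 rose and 6 fell, with the same numbers when adjusted over the list alone. camera did not call this list (adjusted p = 0.133), except among genes without shared reads (0.00239, chosen after the data had been seen). That fit left out OAZ1 and OAZ2, the 2 members that rose, along with SLC3A2 and GPC1, so it tested a different set. Over all tested genes of the list, the camera adjusted p with an estimated correlation was 0.751. All 4 tested genes that passed in the hypusine list of 5 rose (5 when adjusted over the list alone). They include EIF5A and EIF5AL1, which were not measured apart, so the same signal is counted again. camera called the list higher (adjusted p = 0.00953, but 0.751 with an estimated correlation, which was 0.852).

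The change reached far beyond these pathways. Of 11785 genes tested, 2292 were higher and 2510 lower with spermidine, and 6983 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), so 40.7% were called. At an unadjusted p under 0.05 the number was 5798. At least 2-fold changes were found for 762 higher and 506 lower genes. All changes are relative to the scaled coding total, and their median over tested genes was -0.008 on the log2 scale. A change of footprints common to most genes would therefore not be seen. Of all tested genes, 8361 (70.9%) had no overlap between the groups, against 33.3% that chance gives for 2 against 2. Across genes, which are not independent replicates, the changes within the first and within the second number correlated with r = 0.799. The count of higher genes depended on single libraries and on the tool. It was 1450 without Spermidine replicate 1, 1694 without Spermidine replicate 2 and 1439 by DESeq2.

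After OAZ2, large increases by the naming rule were those of SLC45A4, NES, CDH1, HIST1H1D, HMGA1, PRR36, PLEKHG2, ITGA8, HSPA1A and SEMA3A. Linker histone gene HIST1H1D rose from 61.4 ± 2.32 to 462.2 ± 46.9 CPM (7.51-fold, edgeR adjusted p = 7.64e-09). The inducible chaperone gene HSPA1A rose 5.38-fold (edgeR adjusted p = 3.37e-07). The chromatin protein gene HMGA1 rose 7.19-fold (8.36e-06) and the intermediate filament gene NES 8.50-fold (0.000104). SLC45A4, at 1.37 ± 1.06 CPM in DFMO, rose 10.3-fold (5.09e-05) from 11 footprints, where the counting interval of the ratio ran from 5.79 to 21.4. Its log2 change of 3.37 was 2.68 without DFMO replicate 1 and 4.39 without DFMO replicate 2. The remaining members of this group rose between 5.31-fold for SEMA3A and 7.84-fold for CDH1. CDH1 had 14 footprints in the DFMO libraries (counting interval of the ratio 4.6 to 14.7), and its log2 change of 2.97 was 4.57 without DFMO replicate 1 and 2.34 without DFMO replicate 2. OAZ2, CDH1, HIST1H1D, HMGA1, PRR36, PLEKHG2 and HSPA1A held reads shared with other places and are less certain.

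By the naming rule, the largest decreases after AMD1 and AZIN1 were those of FAM13B, SHC2, PPP1R15A, ZNF431, TXNIP, TMEM128, TSC22D3, TTC19, ARRDC3 and ZNF805. FAM13B fell 5.60-fold (edgeR adjusted p = 2.68e-06), and SHC2 had a log2 change of -2.39, which was -3.16 without Spermidine replicate 1. PPP1R15A, also named GADD34, which directs dephosphorylation of eIF2 alpha, fell 4.30-fold (1.25e-05). The arrestin-related genes TXNIP and ARRDC3 fell 4.28-fold and 3.83-fold (8.57e-07 and 2.74e-05). TSC22D3, a glucocorticoid-induced gene, went from 352.7 ± 25.8 to 88.9 ± 8.23 CPM, and the mitochondrial protein gene TTC19 from 186.6 ± 0.373 to 47.4 ± 1.49 CPM (both 1.52e-07). PPP1R15A, ZNF431, TMEM128 and ZNF805 held shared reads.

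**Figure D2:**
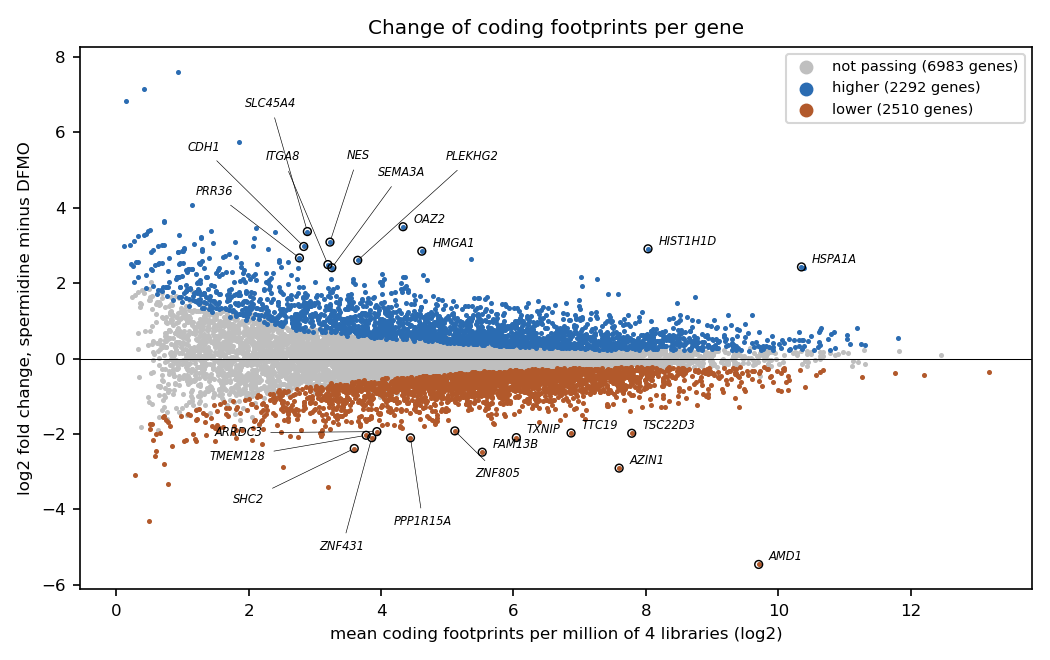
Log2 fold change of coding footprints (vertical, spermidine minus DFMO) against mean coding footprint CPM of the 4 libraries (horizontal, log2) for all 11785 tested genes. Blue points are the 2292 genes higher and brown points the 2510 genes lower at adjusted p under 0.05, and circles mark named genes with large changes, with AMD1 at -5.46 and OAZ2 at 3.50.

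Among 30 gene lists fixed before the data were examined, 25 had enough tested members, and camera called 8 higher and 2 lower with spermidine. Replication-dependent histone genes had the smallest camera p. Of 45 tested, 39 rose and 0 fell (41 rose when adjusted over the list alone), with a median log2 change of 0.86 (camera adjusted p = 5.05e-12, but 0.751 as the adjusted p with an estimated correlation). Besides HIST1H1D, core histone genes HIST1H3A and HIST1H4B rose 3.78-fold and 3.27-fold and linker histone gene HIST1H1B 2.77-fold. All 45 held shared reads, whose amount was not measured, so it is not known how far single histone genes were told apart. Heat shock genes rose in 12 of 22 cases and fell in 0 (13 and 0 when adjusted over the list alone; camera adjusted p = 0.00042). HSPA1B rose 5.30-fold, sharing reads with HSPA1A, the mitochondrial cochaperonin gene HSPE1 rose 3.26-fold and the small heat shock gene HSPB1 3.10-fold. With an estimated correlation the adjusted p was 0.751 for every list that camera called, and fry called 0 of them. In simulated data camera with an estimated correlation missed a list of 30 genes raised 1.5-fold, so its lack of calls cannot decide. The fry adjusted p was 0.0503, upwards, for the histone, cholesterol, proteasome, hypusine and both ribosomal protein lists. It ran from 0.0808 to 0.135 for the others that camera called.

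Genes of the cholesterol synthesis list rose in 18 of 29 cases and fell in 3 (19 and 4 when adjusted over the list alone; camera adjusted p = 0.00042, and 0.751 with an estimated correlation). Squalene epoxidase SQLE rose 2.12-fold, ACAT2 2.00-fold and squalene synthase FDFT1 1.98-fold. Proteasome subunit genes rose in 22 of 31 cases and fell in 0 (22 and 1 when adjusted over the list alone; camera adjusted p = 0.00042, estimated correlation p = 0.751), by small amounts such as 1.60-fold for PSMC2, 1.56-fold for PSMC1 and 1.45-fold for PSMA5. Mitochondrial ribosomal protein genes rose in 26 of 50 cases and fell in 3 (the same when adjusted over the list alone; camera adjusted p = 0.00136, estimated correlation p = 0.751), among them MRPS14 by 2.22-fold and MRPL43 by 2.19-fold.

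Cytosolic ribosomal protein genes and glycolysis genes went both ways. For the first, 30 of 78 rose and 14 fell (the same when adjusted over the list alone), with RPL35A up 2.02-fold and RPS25 up 1.98-fold (camera adjusted p = 0.0421, and 0.751 with an estimated correlation). For the second, 13 of 30 rose and 6 fell (15 and 7 when adjusted over the list alone; camera adjusted p = 0.0421, estimated correlation p = 0.751), with PKM at 1.68-fold, ALDOA at 1.56-fold and GAPDH at 1.45-fold among the members with the smallest p. Both calls ended without DFMO replicate 2, at a camera adjusted p of 0.122 and 0.294, and for the ribosomal protein genes it was also 0.083 without DFMO replicate 1 and 0.114 without Spermidine replicate 2. For glycolysis it was 0.107 without Spermidine replicate 1. Both also ended without a filter (0.108 and 0.0677 by camera) and among genes without shared reads (0.153 and 0.0924). That last fit tested smaller lists, as 42 of the 78 and 26 of the 30 genes held shared reads.

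Stress-response genes under the transcription factor ATF4 fell in 20 of 35 cases and rose in 3 (22 and 3 when adjusted over the list alone), with a median log2 change of -0.48 (camera adjusted p = 0.00042, and 0.751 with an estimated correlation). ATF4 itself went from 252.6 ± 13.6 to 109.5 ± 12.7 CPM, a 2.31-fold decrease (edgeR adjusted p = 5.69e-06). The amino acid carriers SLC7A5 and SLC7A11 fell 2.42-fold and 2.81-fold (1.36e-06 and 8.74e-06), beside SLC3A2. Chaperone and unfolded protein response genes of the endoplasmic reticulum fell in 12 of 27 cases and rose in 2 (the same when adjusted over the list alone; camera adjusted p = 0.0421, estimated correlation p = 0.751). XBP1 fell 2.16-fold, DNAJC3 1.82-fold and SEC61A1 1.60-fold, whereas SDF2L1 rose 2.96-fold. This second call ended without DFMO replicate 1 (adjusted p = 0.177), without Spermidine replicate 2 (0.103) and with all libraries thinned to the smallest coding total, chosen after the data had been seen (0.0662).

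**Figure D3:**
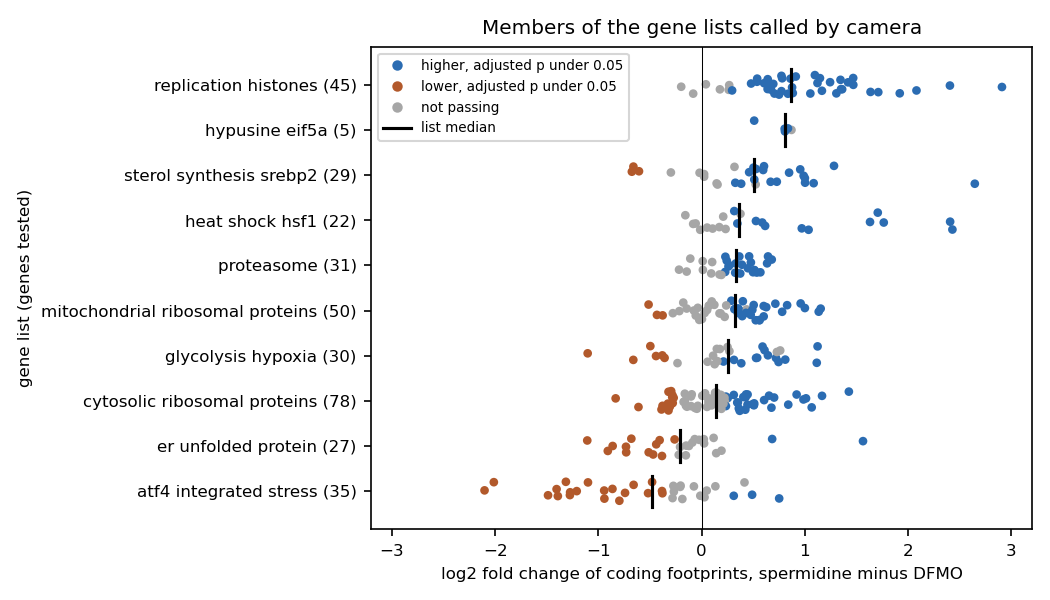
Log2 fold change of coding footprints (horizontal, spermidine minus DFMO) of each tested member of the 10 lists called by camera (vertical, tested members in brackets). Blue and brown points passed the gene test upwards and downwards, grey points did not, and black bars are list medians, from -0.48 for the ATF4 list to 0.86 for the histone list.

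camera made no call for the other tested lists, and in most of them genes moved in both directions. Translation factor genes rose in 11 of 42 cases and fell in 11 (12 and 12 when adjusted over the list alone; camera adjusted p = 0.896). EIF1, which guards start codon choice, fell 2.35-fold and EIF4A2 2.34-fold, while EIF1AX rose 2.23-fold and EIF4B 1.49-fold. Aminoacyl-tRNA synthetase genes gave 4 higher and 5 lower of 20 (5 and 5 over the list alone, 0.734), with AARS down 1.85-fold, YARS down 1.43-fold, QARS up 1.57-fold and FARSA up 1.44-fold. Ribosome assembly genes gave 15 higher and 11 lower of 39, the same when adjusted over the list alone (0.725), with NOLC1 up 1.99-fold, GNL3 up 1.68-fold, POLR1A down 1.73-fold and NOC3L down 1.64-fold. Its median of -0.02 and mean of 0.06 differed in sign. DNA replication genes gave 17 higher and 8 lower of 45 (18 and 8 over the list alone) at a camera adjusted p of 0.0667, and 0.0338 with a minimum mean of 50 counts (adjusted p = 0.751 with an estimated correlation at the usual filter), among them MCM5 up 1.72-fold, DUT up 1.95-fold and CDC45 up 1.67-fold, with UNG down 1.51-fold. In the list of mitosis genes 7 of 40 rose and 12 fell (the same over the list alone, 0.69). KIF4A fell 1.83-fold, TOP2A 1.68-fold and CDK1 1.62-fold, and CCNB1 rose 1.46-fold.

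Oxidative stress genes gave 9 higher and 10 lower of 23 (10 and 10 adjusted over the list alone; camera adjusted p = 0.926), with a median of -0.20 and a mean of 0.06. Heme oxygenase HMOX1 rose 2.56-fold, while FTH1 fell 1.83-fold and TXNRD1 1.56-fold. Of 22 listed selenoprotein genes only 11 were found under the listed names. Of the 8 tested selenoprotein genes 2 rose and 4 fell, the same over the list alone (0.725). MSRB1 rose 2.25-fold, GPX3 rose 1.95-fold, and TXNRD3 fell 1.88-fold, where the TXNRD3 call ended without DFMO replicate 1 (edgeR adjusted p = 0.0862) and that of GPX3 without Spermidine replicate 2 (0.0847). Targets of p53 gave 5 higher and 10 lower of 30, the same over the list alone (0.498), with RPS27L up 2.19-fold, PMAIP1 down 2.40-fold, GADD45A down 1.99-fold and TNFRSF10B down 1.62-fold. Nuclear-encoded respiratory chain genes gave 22 higher and 15 lower of 70 (23 and 15 over the list alone, 0.293), among them COX6B1, up 2.92-fold, ATP5G1, up 2.13-fold, COX7B, up 2.10-fold, and COX6C, up 2.06-fold. Autophagy and lysosome genes gave 12 higher and 6 lower of 40, the same over the list alone (0.276), with GABARAP up 2.36-fold, LAMP1 up 2.18-fold, GABARAPL2 up 1.97-fold and ATG4B down 1.78-fold.

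Immediate early genes gave 2 higher and 5 lower of 24, the same adjusted over the list alone (camera adjusted p = 0.725), with a median of -0.15 and a mean of 0.06. JUNB rose 4.33-fold, while JUN fell 1.54-fold and KLF10 and DUSP1 fell 1.85-fold each. Interferon-stimulated genes gave 4 higher and 0 lower of 17, the same over the list alone (0.176): IFITM1, IFITM2 and IFITM3, which share reads, rose 2.31-fold, 2.77-fold and 2.76-fold, and IFI35 rose 3.05-fold, a call that ended without DFMO replicate 2 (edgeR adjusted p = 0.0678) and without Spermidine replicate 1 (0.218). Genes of the folate cycle and nucleotide synthesis gave 3 higher and 8 lower of 27, the same over the list alone (0.599), with MTR down 1.5-fold, MTHFD1L down 1.45-fold, PRPS1 down 1.38-fold and GMPS up 1.43-fold. Of 2 tested metallothionein genes, MT1X fell 1.83-fold (0.0419, at least 0.0534 without any of the libraries) and MT2A did not pass at -0.19. Protein genes of the mitochondrial genome were not analysed here.

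Markers of other cell types were low and mostly below the filter, and 6 of the 8 tested rose with spermidine. Of 3 tested blood markers, the alpha globin genes HBA1 and HBA2, which share all their reads, rose from 0.679 ± 0.213 to 3.75 ± 0.847 CPM (edgeR adjusted p = 0.006), and CD68 did not pass at 0.33. The epithelial markers CDH1 and EPCAM rose 7.84-fold and 2.49-fold. In the mesenchymal list COL1A1 rose 3.03-fold and COL3A1 3.46-fold, and ACTA2 did not pass at 0.07 (without DFMO replicate 1 it passed, edgeR adjusted p = 0.0484). Without DFMO replicate 1 the log2 change was 2.13 for EPCAM and 2.25 for COL1A1, against 1.32 and 1.60. The COL3A1 call ended without any of the libraries (edgeR adjusted p from 0.07 to 0.125). That of EPCAM ended without DFMO replicate 2 (0.156), Spermidine replicate 1 (0.11) or Spermidine replicate 2 (0.0711). By DESeq2, EPCAM, COL3A1, PAOX, ARG2, MTAP, DOHH, MT1X, GPX3 and IFI35 did not pass, with adjusted p from 0.0735 for GPX3 to 0.206 for MT1X. The level of 3 counts was 0.622 and 0.793 CPM in the DFMO libraries and 0.295 and 0.45 CPM in the Spermidine libraries.

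Most footprints of coding genes lay in coding regions. Their share was 90.0 ± 8.72% in DFMO and 92.7 ± 5.60% in Spermidine (mean ± SD, n = 2), a difference of 2.72 percentage points with an exact two-sided permutation p of 0.667. Within the replicate numbers it was 0.522 and 4.93 points. The leader, the stretch before the start codon, held 5.13 ± 4.60% and 3.93 ± 2.87% (p = 1 by the exact permutation test), and the trailer, the stretch after the stop codon, held 4.92 ± 4.12% and 3.39 ± 2.73% (exact permutation p = 0.667). With 2 libraries against 2 the smallest p is 0.333, so this test could not pass. Each of the 3 differences turned its sign when DFMO replicate 2 or Spermidine replicate 1 was left out, as for the coding share, at -3.44 and -1.24 points. The leader difference of -1.19 points was -0.49 over the genes that pass the coding filter. Single genes held much of some of these shares. OR1F1 held 26.0%, 45.1%, 37.8% and 44% of the leader reads of DFMO replicates 1 and 2 and Spermidine replicates 1 and 2, and CTC1 held 9.1%, 52.3%, 24.4% and 59.5% of the trailer reads.

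The ratio of leader to coding footprints within a gene compares regions of the same mRNA and needs no RNA library. AZIN1 and AMD1 carried more leader footprints for each coding footprint with spermidine. For AZIN1 the leader had 4.64 ± 1.32 footprints per 100 coding footprints in DFMO and 38.7 ± 7.91 in Spermidine (log2 change of the ratio 3.08, SE 0.54). Its leader level itself was 15.9 ± 4.85 CPM and 17.4 ± 0.153 CPM, and its coding level fell. For AMD1 the values were 0.557 ± 0.140 and 6.35 ± 1.76 (3.51, SE 0.80), with the leader level at 9.09 ± 2.39 and 2.36 ± 0.692 CPM. OAZ1, whose coding reads are partly shared, had a lower ratio, 7.31 ± 4.90 against 0.646 ± 0.221 (-3.44, SE 0.66). Its coding level rose, and its leader level was 3.61 ± 2.75 CPM in DFMO and 1.39 ± 0.576 CPM in Spermidine. In none of these did the interaction test of edgeR pass over its 1552 genes, with adjusted p of 0.312 for AZIN1 and OAZ1 and 0.322 for AMD1. It called 0 genes in all, with 159 genes at an unadjusted p under 0.05 (64 higher and 95 lower), and limma voom also called 0. With scaling factors set within each region, chosen after the data had been seen, 3 genes passed, namely AZIN1, AMD1 and OAZ1 (edgeR adjusted p = 0.00825 for each), and without Spermidine replicate 2 the test called 5, OAZ1 among them (0.00403). The changes within the first and second replicate number were 3.57 and 2.57 for AZIN1, 2.98 and 4.06 for AMD1 and -2.99 and -3.72 for OAZ1.

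Among other genes with the smallest p, PEX2, a peroxisome assembly gene, went from 6.99 ± 0.302 to 27.2 ± 0.22 leader footprints per 100 coding footprints (1.95, edgeR adjusted p = 0.322). SNRPG went from 4.91 ± 1.12 to 0.603 ± 0.224 (-3.04, 0.312) and AKIRIN2 from 4.99 ± 1.26 to 0.617 ± 0.387 (-2.90, 0.322). ATF4, whose leader carries known upstream reading frames, had 31.0 ± 3.74 and 29.4 ± 1.97 (-0.07, 0.969), although its coding footprints fell. SAT1 had 21.3 ± 7.14 and 33.3 ± 2.71 (0.64, 0.659) and ODC1 1.60 ± 0.686 and 1.17 ± 0.0669 (-0.37, 0.866). Simulated leader ratios changed 4-fold were recovered for 56.0% of genes, so changes of this size, and smaller ones, could be missed by this test.

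**Figure D4:**
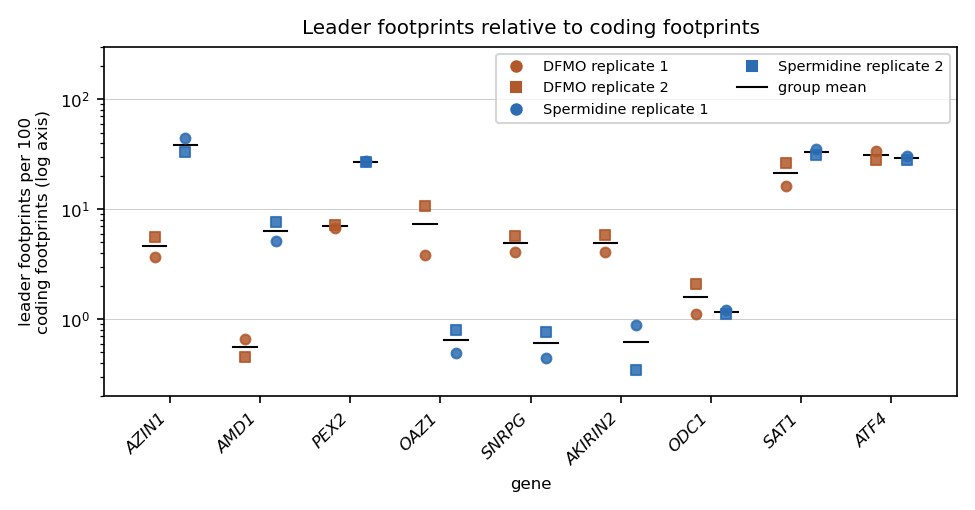
Leader footprints per 100 coding footprints (vertical log axis) of 9 named genes in each library. Circles are replicate 1 and squares replicate 2, brown for DFMO and blue for Spermidine, and black bars are group means, at 4.64 and 38.7 for AZIN1 and at 31.0 and 29.4 for ATF4.

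Trailer footprints relative to coding footprints were lower with spermidine across most genes in the fit, though single genes did not pass. Of 3804 genes tested, 3451 had a fitted decrease, with a median log2 change of -0.88. In the first replicate number the median was -0.91 and in the second -0.84, and 2909 genes were lower in both. The per-library medians were 36.6 and 92.1 trailer footprints per 1000 coding footprints in the DFMO libraries and 19.6 and 51.3 in the Spermidine libraries, so the groups overlapped (exact permutation p = 0.667). The size of the shift changed when a library was left out, which also unbalanced the replicate numbers, whose levels differed. The median change was -1.51 without DFMO replicate 1, -0.16 without DFMO replicate 2, -0.18 without Spermidine replicate 1 and -1.57 without Spermidine replicate 2. Scaling factors set within each region take out a shift common to all genes by construction, and with them the median was 0.06. edgeR called 0 genes, with a smallest adjusted p of 0.925 and 71 genes at an unadjusted p under 0.05, and limma voom called 0 as well. Simulated trailer ratios changed 4-fold were recovered for 3% of genes, so this test had little power.

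Against this general shift, AMD1 had more trailer footprints for each coding footprint, 2.34 ± 1.40 per 100 in DFMO and 11.1 ± 4.67 in Spermidine (log2 change 2.33, edgeR adjusted p = 0.925). TTC4 went from 1.10 ± 0.107 to 4.81 ± 0.336 (2.11), ARMCX6 from 15.5 ± 12.4 to 53.9 ± 43.9 (1.73) and AZIN1 from 3.23 ± 1.25 to 9.11 ± 7.54 (1.29). The antizyme genes went the other way, OAZ1 from 17.2 ± 4.65 to 1.41 ± 0.0111 (-3.58) and OAZ2 from 56.7 ± 3.03 to 9.61 ± 4.70 (-2.64). KIAA0101 had a change of -3.94 and FAM32A of -3.33, ODC1 of -1.29 and ATF4 of 0.79. The edgeR adjusted p was 0.925 for all of these, and only AMD1 passed with scaling factors set within each region (0.0157). The trailer level of AMD1 itself fell from 38.1 ± 22.4 to 4.13 ± 1.8 CPM, and its coding level fell more. Of the genes named here, the trailer level rose for OAZ2 (1.83 ± 0.344 to 3.76 ± 2.53 CPM), TTC4 and ARMCX6. For the others it was lower, as for AZIN1 (11.1 ± 4.52 to 4.56 ± 4.36 CPM) and OAZ1 (8.29 ± 3.23 to 3 ± 0.208 CPM).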

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

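Thinning, the fit without shared reads, scaling within regions and the term for region by replicate number were chosen after the data had been seen; the others were set before. Of the 4802 called genes, 0 turned their direction in any refit of coding counts, and 2 did with all regions summed. Genes higher with spermidine numbered 1439 by DESeq2 and between 1450 and 2057 without a library, against 2292; the cause was not tested. With fewer genes tested, the 7507 without shared reads, 1450 were higher and 1571 lower. Other fits gave 2040 to 3041 higher genes. The replicate block gave 3041 higher and 3253 lower genes, all 4802 called genes among them, and 9 lists, without that of cytosolic ribosomal proteins (adjusted p = 0.0609). Deviations of same-numbered libraries correlated across genes with r = 0.293, which does not settle whether the numbers pair libraries.

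Of the 10 lists called, 0 were called with an estimated correlation, which was 0.584 for histones and 0.586 for heat shock genes. That setting also missed a raised list in simulated data, so it cannot decide. fry called 1 list, of polyamine synthesis and breakdown, as lower, and the cause was not tested. Of 1756 comparisons of 141 named genes, 1700 kept direction and side of the threshold, 41 lost the call, 8 gained it and 7 reversed. Of 323 for the lists, 275 kept both, 33 lost the call, 3 gained it and 12 reversed; of 183 for named region ratios, 152 kept both, 26 gained a call and 5 reversed. All reversed values belong to results that did not pass, and the cause was not tested. SMS was at 0 on the log2 scale with a minimum mean of 50 counts, 0.01 with all regions summed, 0.04 after thinning and from -0.09 to 0.07 without a library. Without a library AZIN2 ranged from -0.38 to 0.06 and ACTA2 from -0.31 to 0.66. The adjusted p of reversed lists was 0.852 for oxidative stress without a filter, 0.972 for translation factors with a minimum mean of 50 counts, and without shared reads 0.702 for translation factors, 0.753 for ribosome assembly and 0.585 for immediate early genes. Without a library it ran from 0.915 to 0.974 for polyamine synthesis, 0.745 to 0.963 for translation factors, 0.389 to 0.98 for tRNA synthetases, 0.897 to 0.951 for oxidative stress and 0.567 to 0.963 for immediate early genes.

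Genes with a changed leader ratio numbered from 0 to 5 without a library, 3 with TMM factors within each region and 161 with a replicate block (region by replicate number term), against 0; limma with a replicate block called 0. For the trailer ratio the numbers were 1 with TMM factors within each region, 514 in limma with a replicate block (508 lower) and 1046 with the region by replicate number term (1038 lower). The last terms take up the difference in region shares between replicate numbers, whose pairing is not stated. Log2 ratio changes without a library ran from -0.82 to 0.09 for the ODC1 leader, -0.2 to 0.05 for the ATF4 leader (0.14 with TMM factors within each region) and -0.16 to 1.94 for the ATF4 trailer. Differences of region shares without a library ran from -4.44 to 2.06 points for the leader, -3.44 to 8.89 for the coding region and -4.44 to 1.38 for the trailer. Leaving out a library also unbalanced the replicate numbers, whose region shares differed, and other causes were not tested. With all libraries thinned to the smallest coding total, 4089 of the 4705 called genes still tested kept their call. Where 1 library was left in a group, it was assumed to vary like the other group. Other pseudocounts and filters meant for normalized values were not run, since the values are counts.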

Other observations

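All tests in this part, of gene families, of noncoding classes and of explanations, were chosen after the results had been seen. Genes grouped by the letters that open their symbol formed 104 families of at least 12 tested genes, and camera called 7 higher and 6 lower with spermidine (Benjamini-Hochberg). With an estimated correlation the adjusted p was 0.912 and 0 passed, and fry also called 0. As the estimated correlation missed a raised list in simulated data, it cannot decide here. Among the lower families, ALG genes, which build the sugar chain for protein glycosylation, fell in 9 of 15 cases and rose in 0 (camera adjusted p = 0.00241). ALG2 changed by -1.59 and ALG6 by -1.02 on the log2 scale. Solute carrier genes fell in 82 of 217 cases and rose in 28 (0.0088), with the nucleotide sugar carriers SLC35B4 at -1.62 and SLC35A3 at -1.71. Transmembrane protein (TMEM) genes fell in 64 of 163 cases and rose in 13 (0.00168), as TMEM38B at -1.38. ZBTB genes fell in 18 of 38 cases and rose in 2 (0.0088), and AP genes, many of them subunits of vesicle adaptors, fell in 12 of 29 cases and rose in 2 (0.0436), with AP3M2 at -1.46.

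Splicing factor genes of the SRSF family rose in 8 of 12 cases and fell in 0 (camera adjusted p = 0.0088, and 0.912 with an estimated correlation), with SRSF6 up by 0.72 and SRSF1 by 0.54. Genes of the COL family rose in 12 of 23 cases and fell in 2 (0.0088), such as the collagens COL25A1 at 1.24 and COL18A1 at 0.77. COL4A3BP, which is not a collagen, fell by 0.73. The remaining higher families, of histone, HSPA and ribosomal protein genes (MRPL, MRPS and RPL), overlap the lists of the report. Genes with RPS symbols, 12 higher and 11 lower of 45, were not called (camera adjusted p = 0.855). Of 954 genes of noncoding classes, edgeR called 0 (145 at an unadjusted p under 0.05, of which 64 were higher and 81 lower; smallest adjusted p 0.131). Some genes had no footprint in either DFMO library. TMEM221 had 64 footprints in the Spermidine libraries, at least 10.9-fold higher (floor of 3 counts over the group, edgeR adjusted p = 0.00046).

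Genes with ZNF symbols, for zinc finger proteins, fell in 217 of 390 cases and rose in 7, with a median log2 change of -0.78 (camera adjusted p = 2.34e-18, and 0.912 with an estimated correlation). Low abundance is argued against, since 0 of 10000 random lists matched on mean expression had a median as low, the lowest being -0.06. After thinning to the smallest coding total the median was -0.79. Scaling takes depth out of a fold change either way, so this bears only on effects of depth at low counts. Reads shared between paralogs may carry much of the pattern, as the 56 ZNF genes without shared reads had a median of -0.18 (95% bootstrap interval over genes -0.37 to 0) and the 334 others -0.92 (-0.98 to -0.82). Genes without such reads may also differ in kind, and an effect of spermidine on this class stays open.

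The trailer ratio was lower with spermidine, with a median log2 change of -0.88 (95% bootstrap interval over genes, not libraries, -0.91 to -0.86), and it ran from -1.57 to -0.16 when a library was left out. The median was -0.88 after thinning as well. Thinning took the same share of the trailer and coding reads of a library, so it could show only effects of depth at low counts. A background of RNA fragments not held by ribosomes could give trailer reads, and 184 untranslated RNAs had a median change of -0.73 per coding footprint (-0.85 to -0.6), with RN7SK and MALAT1 lower in both replicate numbers and RNU11 higher. A lower background and more coding footprints cannot be told apart, because both measures share the coding count. A change in ribosomes beyond the stop codon with spermidine stays open too.

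Replication histone genes were higher with spermidine. A background of unbound RNA would be expected to move them like the untranslated RNAs, whereas their median change was 0.63 within the first and 1.01 within the second replicate number. Whether shared reads contribute cannot be told apart from a change in each gene, since 0 of 45 listed histone genes lacked shared reads. No biological explanation was tested.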
